A study of Homo sapiens with 6 samples.

How the data were processed

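Messenger RNA of HEK-293T cells was measured in 3 libraries labelled WT, which received a non-targeting guide RNA, and 3 libraries labelled C17orf80 knockout, which received a guide against C17orf80. Per the labels' protocols, cells were grown in DMEM with 10% serum and puromycin selection was used to obtain monoclonal cells, RNA was extracted with TRIzol, mRNA was purified on poly-T beads, and libraries were made with a NEBNext Ultra RNA kit, which the labels do not state to be strand-specific. The number of clones behind the 3 libraries was not given in the sources used here. The submitters' processing notes name FastQC 0.11.9, HISAT2 2.2.1, HTSeq 0.12.4, DESeq2, SAMtools 1.3.1 and bedtools 2.30.0 and the GRCh38 build, without the order of steps or the counting options.

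The deposited gene tables hold whole-number counts per gene and library, not normalised. They list 62348 identifiers, of which 61552 are Ensembl genes and 796 are unannotated transcripts; 490 of the latter were tested, with 29 higher and 19 lower by edgeR. Reads in no annotated feature and ambiguous reads were left out of library sizes and tests; they made up 9.18 ± 0.604% and 12.1 ± 0.446% of counted reads in WT and 12.4 ± 3.08% and 11.1 ± 1.19% in the libraries labelled knockout. The deposited coverage files hold a signal at each of the 16569 bases of the mitochondrial chromosome. The deposited coverage values fell on whole multiples of a step that differed between libraries. Within 0.1 step this held for 100% of values below a coverage of 20, and for 78.8% to 92.7% of all values. The coverage had thus been scaled by sequencing depth before deposit. It was used as deposited, although scaling by nuclear TMM sizes had been planned for raw depth; that scaling was run as an alternative. Names and coordinates came from a RefSeq gene table of GRCh38, which matched 87.3% of tested genes.

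Gene counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr defaults, the quasi-likelihood F test with group as the only term, and Benjamini-Hochberg adjustment over 17452 genes at 0.05. Log-CPM values used a prior count of 2. The 31 gene lists, the tests, the rule for named genes and the first set of alternatives were chosen before the data were examined; 30 lists had at least 2 measured members and were tested with camera of limma 3.58.1 at a correlation of 0.01, with an estimated correlation and with fry. The endoplasmic reticulum chaperones were the single list called by camera, and with an estimated correlation 0 lists were called. Genes named in the text are C17orf80, the mitochondrial mRNAs and rRNAs, the 12 protein-coding genes with the largest rise and the 12 with the largest fall (adjusted p under 0.05, at least 2 CPM in each library of the higher group, no overlap between groups, which 3 against 3 libraries give by chance in 10% of genes), up to 4 called members of a called list and up to 2 members per direction of other lists.

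Mean coverage per region (38 regions) and per 100 bp window (166 windows) was tested with limma with a trend on log2 (coverage + 1), so that changes at low coverage are understated. The 5 coverage ratios and the shares of counts were compared by two-sided exact permutation tests. Alternatives were DESeq2 1.42.0 and limma-voom, other scaling factors, other filters, median coverage, a pseudocount of 10, windows of 50 and 200 bp, a replicate block, and each library left out. Added after the data were seen were the removal of a trend with gene span, a fit on the same genes without it, the nuclear TMM scaling of coverage, a coverage slope and the comparison of gene families among genes expressed in WT. In simulated counts for this comparison with 200 genes changed 2-fold or 4-fold among 17040, 37.8% of 2-fold and 95.8% of 4-fold changes were recovered, with 9 false calls. A further set of genes with a smaller shift was left out of the false calls. The simulation used the same dispersions in each library and held no library that stands apart, so these rates may not carry over to the real libraries.

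Gene counts per library ranged from 14982340 to 16278091. For a gene with 0 counts in a group, 3 counts over the group were set as the limit; other ratios of low counts have 95% counting intervals, and both cover counting error only. No libraries were duplicates of each other by a chi-square comparison of counts. No genome sequence was used here, so GC content was not tested. Values of some single list members are not reported here.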

Results

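Poly(A)-selected RNA from HEK-293T cells, a human embryonic kidney line that carries the SV40 large T antigen, was sequenced from 3 wild-type (WT) libraries, treated with a non-targeting guide, and from 3 libraries labelled as C17orf80 knockout. C17orf80, now named MTNAP1, encodes a protein associated with mitochondrial nucleoids, the complexes of mitochondrial DNA and its proteins. The files held whole counts per gene and a coverage value at each base of the mitochondrial chromosome. Gene counts summed to 14982340, 16278091 and 15865404 in WT replicates 1 to 3 and to 15942017, 15982721 and 16122771 in replicates 1 to 3 labelled knockout. Errors after ± are SD over n = 3 libraries per group for levels and standard errors for log2 fold changes, which are labelled knockout over WT. Whether the libraries of a group came from separate cultures was not given in the sources used here. The p-values therefore measure only the spread between these libraries, which may be technical. The cells were monoclonal per the labels, and the number of clones was not given. A difference between clones therefore cannot be told apart from an effect of the guide in the comparisons below.

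One library stood apart within its group. Replicate 1 labelled knockout correlated with replicates 2 and 3 at Pearson's r of 0.932 and 0.945 across genes on log2 CPM (gene counts scaled to library depth), whereas replicates 2 and 3 correlated at 0.987 and each pair of WT libraries at 0.988. Its TMM scaling factor was 0.851, against 1.03 in replicates 2 and 3. Counts on mitochondrial genes made up 11.9% of its gene counts, against 4.53% and 5.00% in replicates 2 and 3. The counts of called list members are therefore given below with and without this library.

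C17orf80 was measured first, since it checks the genotype labels. The transcript (ENSG00000141219, chromosome 17, positions 73232433 to 73248959 on GRCh38) was present in each library labelled knockout and was higher there than in WT, at 27.3 ± 1.72 CPM in WT and 46.9 ± 8.22 CPM in the libraries labelled knockout. It had 397, 451 and 476 counts in WT replicates 1 to 3 and 763, 699 and 698 counts in replicates 1 to 3 labelled knockout. The log2 fold change was 0.78 ± 0.17, with an edgeR quasi-likelihood adjusted p of 0.0232, and was 0.64 without replicate 1 labelled knockout. The direction is opposite to a loss of the transcript, and the label is kept below as the name of the group. The guide position was not given in the sources used here, so a count over the whole gene does not test whether the reading frame was disrupted. The edgeR adjusted p rose to 0.127, 0.117 and 0.0999 on leaving out WT replicates 1, 2 and 3, and to 0.0549 on leaving out replicate 3 labelled knockout.

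**Figure D1:**
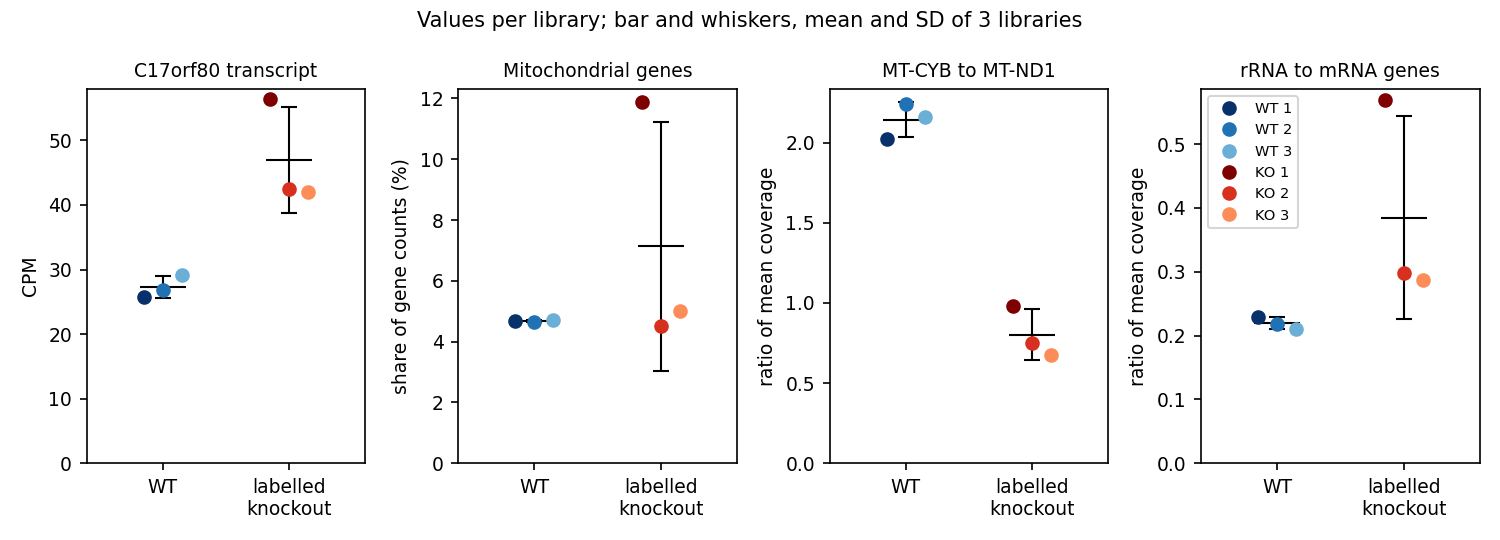
Values per library for the C17orf80 transcript in CPM, the share of gene counts on mitochondrial genes in percent, and the ratios of mean mitochondrial coverage of MT-CYB to MT-ND1 and of rRNA to mRNA genes; points are libraries, and the bar and whiskers are the mean and SD of 3 libraries. C17orf80 was at 27.3 CPM in WT and 46.9 CPM in the libraries labelled knockout, and the MT-CYB to MT-ND1 ratio was 2.14 in WT and 0.801 in the libraries labelled knockout.

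The series title asks how depletion of C17orf80 affects transcription of mitochondrial DNA. Over all 6 libraries none of the 13 mitochondrially encoded mRNAs, which encode subunits of respiratory complexes I, III, IV and V, passed the test, while replicate 1 labelled knockout carried most of the difference in level. MT-ND4L was at 128 ± 20.1 CPM in WT and 408 ± 367 CPM in the libraries labelled knockout (log2 fold change 1.67 ± 0.59). In the same order MT-ND2 was at 1685 ± 30.2 and 3531 ± 2228 CPM (1.07 ± 0.39). MT-ND4 was at 6624 ± 105 CPM in WT and 13915 ± 9838 CPM in the libraries labelled knockout (1.07 ± 0.44). The annotated spans of MT-ND4L and MT-ND4 overlap, as do those of MT-ATP8 and MT-ATP6, so their separate counts are uncertain. In coverage the log2 change was 0.58 for MT-ND4L and 0.54 for MT-ND4. MT-CYB, the cytochrome b of complex III, was the only mRNA with a lower mean, at 3761 ± 30.0 CPM in WT and 2968 ± 2359 CPM (-0.34 ± 0.48). The edgeR adjusted p of the 13 mRNAs ranged from 0.0959 for MT-ND4L to 0.647 for MT-CYB, and 0 mRNAs passed when adjusted over the list alone. At an unadjusted p under 0.05, edgeR gave 3 higher and 0 lower mRNAs, DESeq2 gave 2 higher and 0 lower after adjustment, and limma-voom gave 0 of either. The median log2 fold change of the 13 mRNAs was 0.77 (0.44 by limma-voom), and the list was not called by camera (adjusted p = 0.330; adjusted p = 0.798 with an estimated correlation).

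Without replicate 1 labelled knockout, 5 of the 13 mRNAs were called higher and 5 lower by edgeR. Over all genes the same fit called 4048 higher and 3927 lower among 18133 tested, so calls in both directions, also of small changes, were common in it. Of the complex I subunits, MT-ND4L rose by 0.63, MT-ND2 by 0.42, MT-ND4 by 0.32 and MT-ND1 by 0.26 on the log2 scale, and MT-CO2 of complex IV rose by 0.15. MT-CYB had a log2 fold change of -1.22 (edgeR adjusted p = 1.78e-16), MT-ND6 of -0.67, MT-ND5 of -0.36, MT-ATP6 of -0.26 and MT-CO3 of -0.13. MT-CO1, MT-ND3 and MT-ATP8 did not pass the test in this comparison. The median log2 fold change of the 13 mRNAs was then 0.088. Coverage of the same genes without replicate 1 labelled knockout was tested by limma. Among the mRNA genes only MT-CO2 (log2 change 0.31, adjusted p = 0.0492) and MT-CYB (-1.20, adjusted p = 0.00223) passed. Coverage of MT-ND4L was at 0.31 (limma adjusted p = 0.106) and that of MT-CO3 at -0.00760 (limma adjusted p = 0.928). For the counts of MT-ND5, MT-ND6, MT-ATP6 and MT-CO3 the direction was opposite to that over all 6 libraries.

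The 2 mitochondrial rRNAs had higher means in the libraries labelled knockout, with wide spread. MT-RNR1, the small-subunit rRNA, was at 449 ± 11.8 CPM in WT and 1245 ± 1020.4 CPM in the libraries labelled knockout (log2 fold change 1.47 ± 0.51, edgeR adjusted p = 0.0922), and MT-RNR2, the large-subunit rRNA, at 2425 ± 6.56 CPM in WT and 7547 ± 7514 CPM (1.64 ± 0.63, edgeR adjusted p = 0.118). Both passed when adjusted over the list alone, and both were called higher without replicate 1 labelled knockout, with log2 fold changes of 0.55 and 0.41. Of the 22 mitochondrial tRNA genes only MT-TP had enough counts to be tested. Its log2 fold change was 2.77 ± 0.80 (edgeR adjusted p = 0.0582). As the single tested member it has over the list alone only its unadjusted edgeR p, which was under 0.05. Without replicate 1 labelled knockout MT-TP passed edgeR, at 1.15. Because the libraries were poly(A)-selected, rRNA and tRNA counts cover only the molecules that selection retained.

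Mitochondrial genes together took 4.68 ± 0.0321% of the gene counts in WT and 7.13 ± 4.11% in the libraries labelled knockout. The difference of 2.45 percentage points had a two-sided exact permutation p of 0.4, where 0.1 is the smallest p that 3 against 3 libraries can give. It was 0.0848 points without replicate 1 labelled knockout. For the mRNAs alone the shares were 4.38 ± 0.0319% and 6.33 ± 3.42% (exact permutation p = 0.7).

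Coverage along the mitochondrial chromosome differed in shape between the groups, with MT-CYB low relative to the genes near the start of the heavy-strand transcription unit. The ratio of mean coverage of MT-CYB (positions 14747 to 15887) to MT-ND1 (positions 3307 to 4262) was 2.14 ± 0.111 in WT and 0.801 ± 0.160 in the libraries labelled knockout, a 2.68-fold lower ratio. Each library labelled knockout lay below each WT library, at 0.980, 0.752 and 0.672 against 2.02, 2.24 and 2.16 (exact permutation p = 0.1, the smallest possible; adjusted p = 0.167 over 5 ratios). The ratio of gene counts of the same genes was 2.68 ± 0.0457 in WT and 1.05 ± 0.161 in the libraries labelled knockout (exact permutation p = 0.1). The ratio of rRNA to mRNA coverage was 0.219 ± 0.00946 in WT and 0.385 ± 0.159 in the libraries labelled knockout, higher in 3 of 3 (exact permutation p = 0.1, adjusted p = 0.167); its log2 change was 0.81, and 0.42 without replicate 1 labelled knockout.

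The ratio of the noncoding control region was also higher in each library labelled knockout than in each WT library. The ratios of MT-ND6 and of the tRNA genes overlapped between the groups. The control region stood at 0.0246 ± 0.00189 of mRNA coverage in WT and at 0.0376 ± 0.0127 in the libraries labelled knockout (exact permutation p = 0.1, adjusted p = 0.167). Its log2 change was 0.61, and 0.18 with median in place of mean coverage and 0.30 without replicate 1 labelled knockout. The control region did not move as a whole. Without replicate 1 labelled knockout, at the deposited scale, the window at positions 16101 to 16200 rose by 0.78 on the log2 scale (limma adjusted p = 0.00643). The windows at positions 101 to 200 and 201 to 300 changed by -0.55 and -0.54 (limma adjusted p = 0.0211 and 0.0484). Coverage of MT-ND6, the mRNA encoded on the other strand, relative to MT-CO1 was 0.305 ± 0.0421 in WT and 0.233 ± 0.103 in the libraries labelled knockout (exact permutation p = 0.3, adjusted p = 0.375; log2 change -0.39, and -0.82 without replicate 1 labelled knockout). The tRNA genes stood at 0.194 ± 0.0140 and 0.198 ± 0.0886 of mRNA coverage (exact permutation p = 1), a log2 change of 0.030 that was 0.36 without replicate 1 labelled knockout. Coverage held both strands together, so transcripts of opposite strands over one position were not separated.

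**Figure D2:**
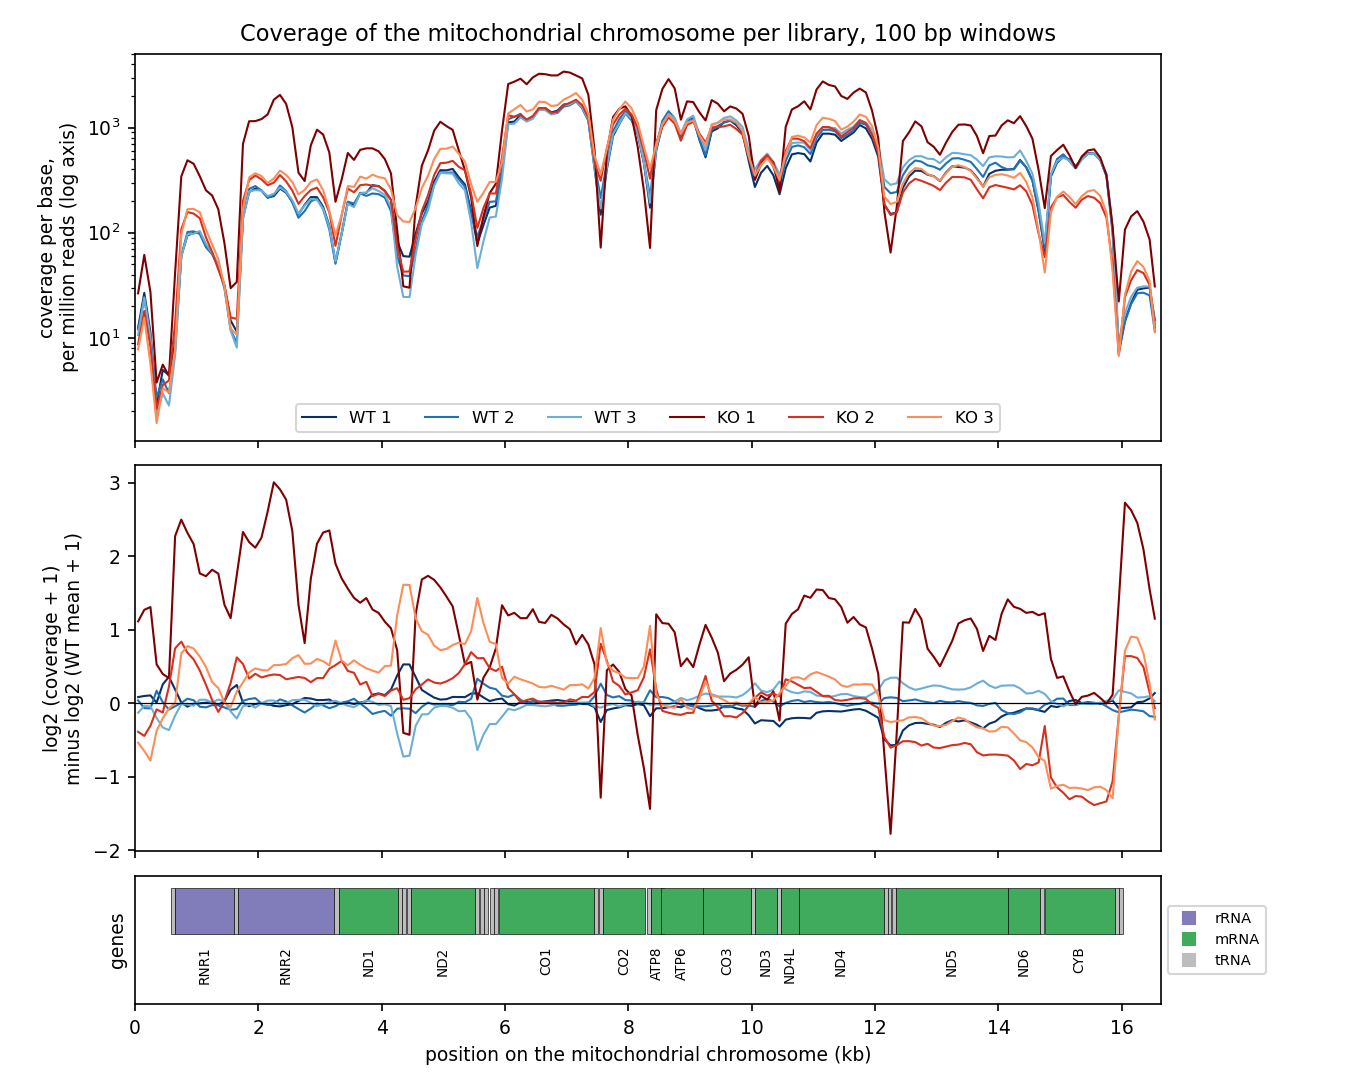
Coverage of the mitochondrial chromosome in 100 bp windows for each library, as deposited (top, log axis), as the log2 difference from the WT mean (middle) and with the annotated genes (bottom), against position in kb. Replicate 1 labelled knockout (KO 1) lies above the others over most of the chromosome, and replicates 2 and 3 (KO 2, KO 3) lie above the WT mean over most of the rRNA genes and below it over MT-CYB, where their coverage was 179.7 and 193 against 429 in WT.

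Tested region by region at the deposited scale, the mean coverage of MT-RNR2 was 199.8 ± 0.659 in WT and 523 ± 435 per base, in the deposited depth-scaled units, in the libraries labelled knockout (log2 change 1.08 ± 0.48), that of MT-ND2 247 ± 16.6 in WT and 461 ± 154 (0.84 ± 0.29) and that of MT-CYB 429 ± 1.04 in WT and 289 ± 178 (-0.73 ± 0.38). At this scale MT-CYB was at 494 in replicate 1 labelled knockout, above the 428 to 430 of the WT libraries. The lower mean thus rests on replicates 2 and 3, at 179.7 and 193. None of the 38 regions and none of the 166 windows of 100 bp passed limma with Benjamini-Hochberg adjustment, while 1 region and 15 windows were higher and 0 lower at an unadjusted p under 0.05. Taken as shares of each library's own mitochondrial coverage, MT-CYB was the single region called, with a log2 change of -1.12 ± 0.20 (limma adjusted p = 0.0480), and the 10 windows called lower lay between positions 14901 and 15900, inside or at the end of MT-CYB. Without replicate 1 labelled knockout, at the deposited scale, 54 windows were called higher and 23 lower. MT-CYB then fell by 1.20 on the log2 scale (limma adjusted p = 0.00223). MT-RNR2 was then at 0.44 and MT-ND2 at 0.60 (limma adjusted p = 0.0704 for each). Neighbouring windows share reads and are not independent.

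Across the genome, 1507 genes were higher and 1134 lower in the libraries labelled knockout among 17452 tested (edgeR adjusted p under 0.05), and 1028 and 655 of these changed by at least 2-fold. The largest changes were between no counts and clear expression. The rule for naming these genes required expression in each of the 3 libraries of the higher group and no overlap between groups. EPDR1, an ependymin-related lysosomal glycoprotein, had 0 counts in the 3 WT libraries and 36.2 ± 3.98 CPM in the libraries labelled knockout, at least 590.2-fold higher. The neuronal intermediate filament gene INA was at least 438-fold higher, the cationic amino acid transporter gene SLC7A3 at least 254-fold, and BEX1 at least 490.3-fold. SFRP1, an extracellular WNT antagonist, had 26.8 ± 0.887 CPM in WT and 0 counts in the libraries labelled knockout, at least 418-fold lower, and GSPT2, a translation termination factor gene on the X chromosome, was at least 381-fold lower. These bounds set 3 counts over the group in place of 0 and, like the counting intervals, cover counting error only.

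The other named genes of largest rise were LRFN5, PARP9, GALC, TNFRSF10D, ESRRG, ZNF229 and NPY1R, each with 0 counts in WT and at least 70.4-fold (NPY1R) to 208-fold (LRFN5) higher. PARP9 and DTX3L, neighbouring genes on chromosome 3 whose products form one complex in the DNA damage and interferon response, both rose, DTX3L from 1 count in WT to 21.0 ± 11.9 CPM, a ratio of 974 with a 95% counting interval from 174 to 38522. Their annotated spans overlap at the ends, and strand was not given for the counts. Among the falls were the cancer-testis genes MAGEA3, MAGEA6, CSAG3 and SAGE1 on the X chromosome. MAGEA6 had 111 ± 3.62 CPM in WT and 0.0805 ± 0.0698 CPM in the libraries labelled knockout, a 1298-fold ratio with a 95% counting interval from 507 to 4766; MAGEA3 and MAGEA6 are near-identical copies, so the split of reads between them is uncertain. GTSF1, a cofactor of piRNA-guided silencing, fell from 32.0 ± 3.33 CPM to 1 count, and ZC3HAV1L, GABRA3, ZNF334, B3GALNT1 and HTR2C had 0 counts in the libraries labelled knockout, at least 69.5-fold (HTR2C) to 304-fold (ZC3HAV1L) lower. All 24 genes passed edgeR over all 6 libraries, as the rule that picked them required, with adjusted p up to 0.00515. They also passed without replicate 1 labelled knockout, on libraries that the rule had used.

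**Figure D3:**
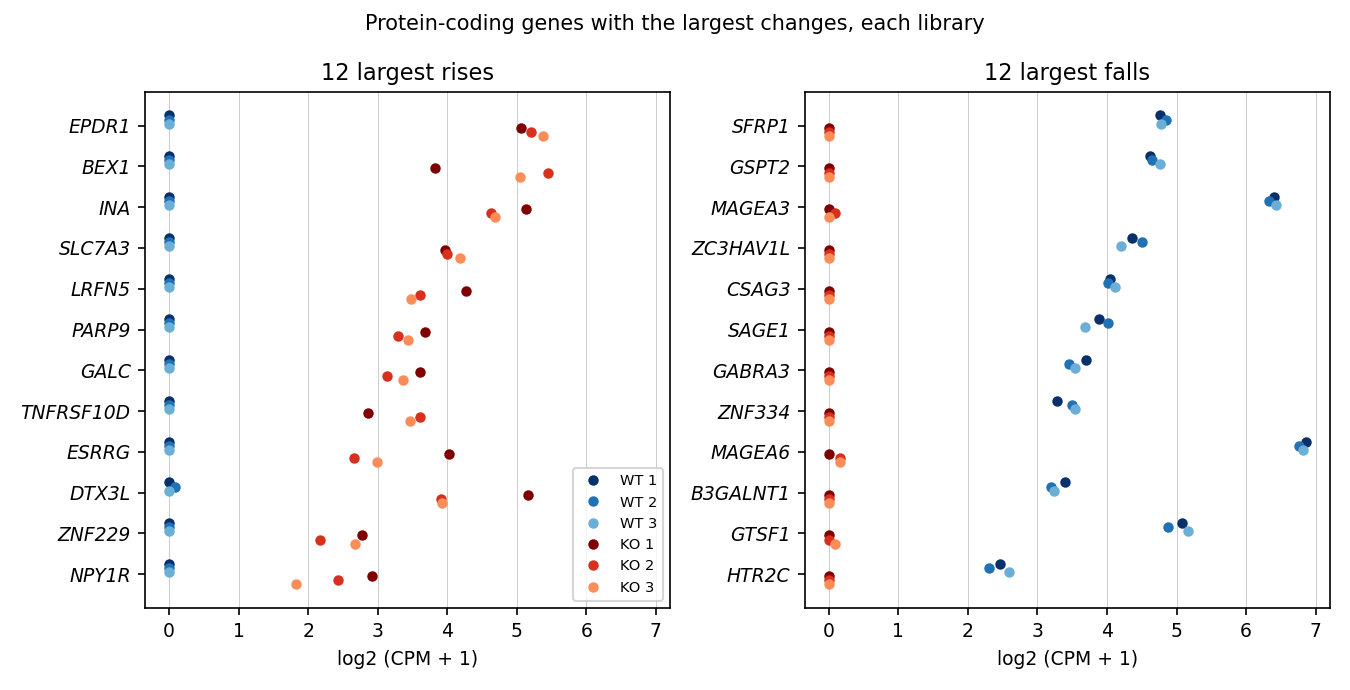
Expression as log2 (CPM + 1) in each library of the 12 protein-coding genes with the largest rise and the 12 with the largest fall; each point is 1 library. The rule that picked these genes required no overlap between the 3 libraries labelled knockout (KO) and the 3 WT libraries, so their separation was fixed by it. EPDR1 was at 36.2 CPM against 0 counts in WT, and SFRP1 at 26.8 CPM in WT against 0 counts.

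The number of genes called depended on the libraries used. It was 663, 670 and 644 without WT replicates 1, 2 and 3, 2706 and 1173 without replicates 2 and 3 labelled knockout, and 7975 (4048 higher, 3927 lower) among 18133 tested without replicate 1 labelled knockout. The counts of list members called without replicate 1 labelled knockout are to be read against that share of all genes. Of the 2641 genes called over all libraries, 660, 669 and 641 were called in the same direction without WT replicates 1, 2 and 3, and 2640, 2165 and 1147 without replicates 1, 2 and 3 labelled knockout. Of the nuclear genes of the fixed lists, 35 rose and 47 fell by edgeR over all libraries, 152 and 167 without replicate 1 labelled knockout, 37 and 40 without replicate 2 and 15 and 11 without replicate 3. They were 6 and 7, 7 and 7 and 6 and 7 without WT replicates 1, 2 and 3. Of 65 called list members named here, 12, 13 and 12 kept their call without WT replicates 1, 2 and 3, 56 without replicate 2 and 25 without replicate 3 labelled knockout. The 11 that kept it whichever library was left out were MRPS6, FH, FBN1, SPARC, COL5A1, INA, NEFL, WT1, EYA1, COL3A1 and LAMB3.

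Of 18 measured genes of the endoplasmic reticulum folding machinery 5 fell, 0 rose and 13 did not pass edgeR. The list was the single one called by camera, though not with an estimated correlation or a replicate block, with a median log2 fold change of -0.39 (camera adjusted p = 0.0276; adjusted p = 0.798 with an estimated correlation). 0 rose and 6 fell when adjusted over the list alone. At an unadjusted p under 0.05 edgeR gave 0 higher and 9 lower, and after adjustment DESeq2 gave 0 and 7 and limma-voom 0 and 5. PDIA4, a protein disulfide isomerase, was at 488 ± 11.8 CPM in WT and 191 ± 56.8 CPM in the libraries labelled knockout (log2 fold change -1.35 ± 0.23, edgeR adjusted p = 0.0117). The chaperone HSPA5 (BiP) was at 879 ± 34.3 CPM in WT and 571 ± 12.3 CPM (-0.62 ± 0.12), its co-chaperone DNAJB11 at 45.0 ± 1.71 CPM in WT and 27.9 ± 1.16 CPM (-0.69 ± 0.13), and CRELD2 at 66.3 ± 6.15 CPM in WT and 29.4 ± 9.02 CPM (-1.17 ± 0.24). Without replicate 1 labelled knockout 12 members fell and 1 rose (camera adjusted p = 0.00303). By edgeR 0 members were called with any 1 WT library left out, 5 without replicate 2 labelled knockout and 1 without replicate 3. Each of the 9 other splits of the 6 libraries into 3 and 3 called 2 to 6 lists, against 1 in the real split. Fry, which does not compare a list with other genes, called this list, complex II, the matrix and adhesion genes and the fibroblast markers lower, and mitochondrial transcription and RNA processing, the interferon-stimulated genes and the neuronal markers higher.

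Extracellular matrix and adhesion genes moved both ways, and the list was not called (camera adjusted p = 0.187). Of 24 measured members 7 fell and 2 rose, and 9 fell and 4 rose when adjusted over the list alone. Leaving out replicate 1 labelled knockout, 7 rose and 12 fell, and called members numbered at most 5 with a WT library left out, 9 without replicate 2 labelled knockout and 6 without replicate 3. SPARC, a collagen-binding matrix glycoprotein, was at 72.9 ± 2.52 CPM in WT and 4.91 ± 0.984 CPM in the libraries labelled knockout (log2 fold change -3.89 ± 0.19), and the collagen gene COL5A1 at 49.8 ± 1.05 CPM in WT and 9.15 ± 1.85 CPM (-2.44 ± 0.18). The fibrillin gene FBN1 rose from 5.65 ± 0.808 to 31.5 ± 12.4 CPM (2.48 ± 0.30), and LOX, the collagen cross-linking lysyl oxidase, by 1.37 ± 0.23 on the log2 scale. The edgeR adjusted p of these 4 genes ranged from 1.20e-04 to 0.0103.

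Of 12 measured interferon-stimulated genes 4 rose and 0 fell by edgeR, the rises including IFIT1 (log2 fold change 1.05 ± 0.19, edgeR adjusted p = 0.0126) and IFIT5 (0.85 ± 0.17). 5 rose and 1 fell when adjusted over the list alone. At an unadjusted p under 0.05 edgeR gave 6 higher and 1 lower, and after adjustment DESeq2 gave 5 and 1 and limma-voom 3 and 0. The list had a median log2 fold change of 0.71 and was not called (camera adjusted p = 0.218). In glycolysis 4 of 22 genes fell and 0 rose by edgeR, including the enolase gene ENO1 (-0.75 ± 0.13, edgeR adjusted p = 0.0136) and the glucose transporter gene SLC2A1 (-0.72 ± 0.14), without a call for the list (camera adjusted p = 0.168). 0 rose and 4 fell when adjusted over the list alone. At an unadjusted p under 0.05 edgeR gave 1 higher and 6 lower, and after adjustment DESeq2 gave 0 and 5 and limma-voom 0 and 4. Of 23 cholesterol biosynthesis genes 3 rose and 0 fell by edgeR, with HMGCS1 at 1.01 ± 0.14 and MSMO1 at 0.80 ± 0.14 (edgeR adjusted p of 0.00512 and 0.0124). 4 rose and 0 fell when adjusted over the list alone. At an unadjusted p under 0.05 edgeR gave 7 higher and 1 lower, and after adjustment DESeq2 gave 6 and 0 and limma-voom 3 and 0. Leaving out replicate 1 labelled knockout, 7 rose and 1 fell among interferon-stimulated genes, 3 rose and 11 fell in glycolysis and 9 rose and 4 fell in cholesterol biosynthesis. Called members of each of these 3 lists numbered at most 1 with a WT library left out, 4 without replicate 2 labelled knockout and 1 without replicate 3.

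Nuclear genes for mitochondrial DNA upkeep and expression changed in both directions. Of 24 measured genes of mitochondrial DNA replication and the nucleoid 2 rose and 4 fell: PRIMPOL, a primase-polymerase, rose by 1.55 ± 0.26 and the exonuclease gene EXOG by 0.88 ± 0.19 on the log2 scale, while ATAD3B changed by -0.73 ± 0.15 and the protease gene LONP1 by -1.07 ± 0.26 (edgeR adjusted p from 0.0112 to 0.0374). Of 30 genes of mitochondrial transcription and RNA processing 3 rose and 1 fell. TFB2M, the transcription factor that opens mitochondrial promoters, was at 8.04 ± 0.968 CPM in WT and 16.9 ± 0.783 CPM in the libraries labelled knockout (1.07 ± 0.17, edgeR adjusted p = 0.00903), MTERF1, a mitochondrial transcription termination factor gene, rose by 0.93 ± 0.18, and FASTK, which binds mitochondrial RNA, changed by -1.55 ± 0.38 (edgeR adjusted p = 0.0365). Among nucleotide supply genes 1 of 15 rose (RRM2, 0.73 ± 0.14) and 1 fell (SLC25A33, -0.62 ± 0.13). Adjusted over the list alone, 5 rose and 6 fell in the first list, 3 rose and 1 fell in the second and 1 rose and 2 fell in the third. In the same order, 8 rose and 10 fell, 10 rose and 5 fell and 5 rose and 5 fell without replicate 1 labelled knockout. Called members of each list numbered at most 1 with a WT library left out, 7 without replicate 2 labelled knockout and 1 without replicate 3. The nucleotide supply list had a median below and a mean above 0. None of these 3 lists was called by camera (adjusted p of 0.610, 0.413 and 0.944).

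Few nuclear subunits of the respiratory complexes passed the test. For complex I 2 of 35 genes fell and 0 rose by edgeR (NDUFB5, -0.61 ± 0.15; NDUFA11, -1.19 ± 0.30), for complex II 1 of 4 fell (SDHB, -0.53 ± 0.13), for complexes III and IV 0 of 9 and 0 of 11 passed edgeR, and for complex V 1 of 18 fell (ATP5PB, -0.88 ± 0.14). At an unadjusted p under 0.05 edgeR gave for complex I 2 higher and 6 lower, and after adjustment DESeq2 gave 2 and 6 and limma-voom 0 and 2. For complex III, 1 gene was higher and 3 lower at an unadjusted edgeR p under 0.05, DESeq2 called 1 higher and limma-voom 0, and for complex IV each of these counts was 0. Adjusted over the list alone, 2 fell in complex II and 1 in complex V, and 0 genes passed in complexes I, III and IV. Leaving out replicate 1 labelled knockout, 6 rose and 7 fell in complex I, 0 rose and 2 fell in II, 1 rose and 3 fell in III, 0 rose and 1 fell in IV and 4 rose and 2 fell in V by edgeR. Camera adjusted p over these 5 lists ranged from 0.280 to 0.413. Of 72 mitochondrial ribosomal protein genes 2 rose (MRPL58, 0.85 ± 0.17; MRPS7, 0.74 ± 0.19) and 3 fell, led by MRPS6 (-1.21 ± 0.17) and MRPS14 (-0.73 ± 0.13). Of 77 cytosolic ribosomal protein genes 1 rose (RPS3A, 0.91 ± 0.15) and 3 fell, with RPL21 at -0.70 ± 0.14 and RPS20 at -0.80 ± 0.18. Adjusted over the list alone, 1 rose and 2 fell in the mitochondrial and 1 rose and 1 fell in the cytosolic list, and without replicate 1 labelled knockout 20 rose and 16 fell of 73 and 18 rose and 18 fell of 77. Called members of each of these 7 lists numbered at most 1 with a WT library left out, 3 without replicate 2 labelled knockout and 3 without replicate 3. The median of the cytosolic list was -0.24 (camera adjusted p = 0.168) and 0.012 and -0.45 without replicates 1 and 2 labelled knockout, and that of the mitochondrial list -0.15, 0.032 and -0.28.

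Stress and metabolic lists held scattered changes. Of 34 targets of ATF4 and the integrated stress response 2 rose (ASNS, 0.80 ± 0.21; WARS1, 0.68 ± 0.18) and 3 fell, including CTH (-0.67 ± 0.13) and SARS1 (-0.51 ± 0.12). Of 17 mitochondrial chaperones and proteases AFG3L2 (0.85 ± 0.14) and HSPD1 (0.57 ± 0.15) rose and LONP1 fell. In the tricarboxylic acid cycle 2 of 21 genes rose (FH, 1.23 ± 0.16; SUCLG2, 0.66 ± 0.15) and SDHB fell. Hypoxia-inducible genes gave 2 rises (LOX; ADM) and 2 falls (P4HA1, -0.65 ± 0.13; SLC2A1) of 18, with a median below and a mean above 0. Mitochondrial dynamics and mitophagy gave 1 rise (PPARGC1B, 0.82 ± 0.17) and 2 falls (among them MFN2, -0.51 ± 0.13) of 22, and NRF2 antioxidant genes 2 rises (NQO1, 1.10 ± 0.20; GCLC, 0.56 ± 0.14) and 1 fall (PGD, -0.53 ± 0.13) of 18. Of 22 p53 targets FAS rose (0.95 ± 0.18) and PLK3 fell (-1.48 ± 0.37), and of 31 cell cycle and DNA replication genes 2 rose (BIRC5, 0.81 ± 0.12; CCNA2, 0.99 ± 0.20) and 3 fell, including RFC4 (-0.85 ± 0.19) and CDC45 (-0.66 ± 0.18). Adjusted over the list alone the counts were the same in 5 of these lists, while in the tricarboxylic acid cycle 2 rose and 3 fell, among NRF2 genes 3 rose and 1 fell and among p53 targets 1 rose and 0 fell. Leaving out replicate 1 labelled knockout, 11 rose and 12 fell among ATF4 targets, 7 rose and 2 fell among chaperones and proteases, 3 rose and 8 fell in the tricarboxylic acid cycle and 5 rose and 5 fell among hypoxia-inducible genes. Likewise 2 rose and 14 fell for dynamics and mitophagy, 9 rose and 4 fell for NRF2 genes, 3 rose and 7 fell for p53 targets and 8 rose and 9 fell for cell cycle genes. Called members of each list numbered at most 1 with a WT library left out, 5 without replicate 2 labelled knockout and 2 without replicate 3. Camera called none of these 8 lists (adjusted p from 0.413 to 0.638), and each named rise and fall had an edgeR adjusted p under 0.05.

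Lineage markers were called in both directions. Of 8 measured neuronal markers INA rose, and NEFL (-1.48 ± 0.17) and GAP43 (-1.05 ± 0.25) fell; the median was -0.21, also with INA at its bound, and ranged over -0.50 to -0.0682 with 1 library left out, while the mean, which rests on INA, lay above 0, camera pointed down and fry up. Of 11 kidney lineage markers the transcription factor gene WT1 rose (1.67 ± 0.20) and EYA1 fell (-1.41 ± 0.21), with a median above and a mean below 0. Of 8 fibroblast markers LUM rose (1.26 ± 0.34) and COL3A1 (-2.43 ± 0.23) and COL1A1 (-0.82 ± 0.20) fell, again with a median above and a mean below 0. Of 3 measured squamous markers LAMB3 rose (1.78 ± 0.27) and SFN fell (-1.82 ± 0.49), and of 2 measured blood markers 0 passed edgeR over all genes, while 1 was lower at an unadjusted p under 0.05, by DESeq2, by limma-voom and when adjusted over the list alone. Leaving out replicate 1 labelled knockout, 3 rose and 2 fell of 9 neuronal, 4 rose and 3 fell of 11 kidney, 1 rose and 2 fell of 9 fibroblast, 1 rose and 1 fell of 4 squamous and 0 rose and 1 fell of 2 blood markers. Called members of each list numbered at most 2 with a WT library left out, 3 without replicate 2 labelled knockout and 2 without replicate 3. In the 4 other lists the counts adjusted over the list alone were the same as over all genes. Camera adjusted p over these 5 lists ranged from 0.451 to 0.818.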

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

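Of the tests in this part, the removal of the gene-length trend as the whole difference was written before its result was seen, and the others were chosen only after.

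Reads in no annotated feature, which enter no comparison of genes, made up 12.4 ± 3.08% of counted reads in the libraries labelled knockout and 9.18 ± 0.604% in WT (exact permutation p = 0.1, the smallest possible). They stood out as a signal outside the measured genes above the control level, with 15.9% in replicate 1 labelled knockout and 10.4% and 10.8% in replicates 2 and 3.

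Replicate 1 labelled knockout differed from replicates 2 and 3 with gene length: Spearman's rho of the difference with annotated gene span was 0.527 across 13085 protein-coding genes, which are not independent, against -0.234 between replicates 2 and 3 and -0.120 to 0.0813 between WT libraries. The fitted trend with gene span is not the whole difference. The SD of the difference went from 0.803 to 0.662 on removing the trend, against 0.191 between replicates 2 and 3. It was taken over genes of mean log-CPM above 3, a filter that the prediction did not name. This filter was applied separately before and after removal, so the genes may differ slightly. Transcript length was not tested. Mixing or a swap with WT is argued against by 19 genes silent in replicates 2 and 3, whose summed CPM in replicate 1 was 0.0995% of WT. Another 25 genes, silent in WT and on in replicates 2 and 3, had in replicate 1 117% of their summed level there. Replicate 1 thus shared both gene patterns with replicates 2 and 3. An effect of the knockout could be shared between clones, so this does not settle whether replicate 1 was another clone. RNA quality, another clone or another preparation may lie behind the rest. None was tested, and GC content could not be. These stay open.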

How the results depend on the processing

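Of the alternatives reported here, the gene-length trend removal, the fit on the same genes without it and nuclear TMM scaling of coverage were chosen only after the data were seen. No gene called over all 6 libraries changed sign under any alternative fit. Leaving out 1 library gave 401 to 4048 higher and 243 to 3927 lower genes, DESeq2 2340 and 1866, and removal of the gene-length trend 1732 and 1725 among 15214 genes with an annotated span, against 1428 and 1116 on the same genes without the removal. With the replicate block the counts were 610 and 359, 0 lists were lower, C17orf80 was at 0.77 (edgeR adjusted p = 0.0829), the mitochondrial mRNA median at 0.39 (past camera's unadjusted threshold) and the cholesterol list at -0.029. Same-numbered libraries did not deviate together (correlations -0.0585, -0.0289 and 0.00216, no library closest to its own number), so no pairing by number was seen. Replicate 1 dominates the deviations of the libraries labelled knockout, so a weak pairing could be missed and is not excluded. C17orf80 ranged over 0.64 to 0.86 with 1 library left out. Mitochondrial mRNAs called higher numbered 0 to 5 and lower 0 to 5 with 1 library left out, 2 higher with DESeq2 and 4 without a filter; their median ranged over 0.088 to 0.99, and was 0.70 without a filter (past camera's unadjusted threshold, as without replicate 2 or 3 labelled knockout) and 0.44 with limma-voom. Lists called lower numbered 1 to 2 with 1 library left out, 0 with an estimated correlation and 4 with fry, which called 3 higher.

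For coverage, 1 library left out gave 0 to 3 regions and 0 to 54 windows higher, and 0 to 1 and 0 to 23 lower; shares of own coverage gave 1 region and 10 windows lower. The tRNA to mRNA ratio ranged over -0.23 to 0.36. Of 38 regions 5 of 13 mRNA and 9 of 22 tRNA genes turned sign in coverage change with 1 library left out, and 0 rRNA genes; tRNA genes included MT-TD (-0.45 to 0.96), MT-TK (-0.42 to 0.91), MT-TQ (-0.10 to 0.93) and MT-TE (-0.64 to 0.35). The mRNA genes were MT-ATP6 (-0.066 to 0.39), MT-CO3 (-0.00760 to 0.33), MT-ND3 (-0.026 to 0.18), MT-ND5 (-0.42 to 0.36) and MT-ND6 (-0.65 to 0.40). As shares of own coverage 4 tRNA and 5 mRNA genes turned sign; of the latter MT-CO2 was at -0.12, MT-ATP6 -0.16, MT-CO3 -0.19, MT-ND3 -0.30 and MT-ND5 -0.34. MT-ND6 was at 0.038 scaled to assigned gene counts, 0.13 with nuclear TMM, 0.042 with medians and 0.00154 with a pseudocount of 10. Log2 changes of counts that turned sign with 1 library left out, among the genes picked by the naming rule, were MT-ATP6 (-0.26 to 0.53), MT-CO3 (-0.13 to 0.56), MT-ND5 (-0.36 to 1.34), MT-ND6 (-0.67 to 0.92), SDHD (-0.11 to 0.22) and COX6A1 (-0.12 to 0.41). List medians that did so were nucleotide supply (-0.16 to 0.057), mitochondrial ribosomal (-0.28 to 0.032), cytosolic ribosomal (-0.45 to 0.012), ATF4 (-0.30 to 0.013), cholesterol (-0.072 to 0.11), NRF2 (-0.033 to 0.32), fibroblast (-0.022 to 0.16) and squamous (-0.29 to 0.38). The cause was not tested. Of the other values of named genes, lists and regions under an alternative, 2239 kept their direction and side of the threshold or, for gene counts, stayed within the range allowed for counts, while 270 lost and 95 gained a call in the same direction. Genes changed at least 2-fold numbered 398 to 1288 higher and 230 to 924 lower with 1 library left out. Leaving out a library also leaves fewer samples, and depth limits statements on genes of few counts.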

Other observations

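The tests in this part, including the gene families, their definitions and the members named, were chosen only after the data had been seen, apart from the coverage ratio and C17orf80 with a library left out, which were planned. Of 464 zinc finger genes named ZNF, ZFP, ZSCAN or ZKSCAN, many of them transcriptional repressors, 137 rose and 16 fell by edgeR, and 231 and 52 of 469 without replicate 1 labelled knockout. Of 15 genes named for the MAGE and other cancer-testis antigen families 10 fell and 0 rose by edgeR (DESeq2 and limma-voom 11 and 0), 12 of 15 without that library, with MAGED4 from 6.84 ± 0.925 to 1.89 ± 0.455 CPM. Several are near-identical copies, and 4 of them are among the largest falls, which prompted the family. Clustered protocadherins, neuronal adhesion receptors encoded in tandem on chromosome 5, were called higher in 23 of 24 tested members (limma-voom 23; DESeq2 23, and 1 lower; 24 of 25 without that library). However, 21 of the 24 had a WT mean below 1 CPM and so passed the expression filter through the libraries labelled knockout, which largely fixes that count. PCDHGA1 rose from 0.140 ± 0.149 to 21.7 ± 6.63 CPM and PCDHB13 from 0.0408 ± 0.0707 to 12.8 ± 3.41 CPM, while PCDHGC4 was at 3.11 ± 0.527 in WT and 1.54 ± 0.359 CPM (edgeR adjusted p = 0.0656). Members of the gamma cluster share exons, so their separate counts are uncertain.

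The families were compared with the rest of 12388 protein-coding genes with a WT mean of at least 1 CPM, without the 24 genes of largest change, by Fisher's exact test adjusted over 24 tests of 12 definitions, some of them overlapping. Of 444 zinc finger genes 125 rose and 15 fell (Fisher's exact adjusted p = 7.67e-35 for rises), and of 11 MAGE and cancer-testis genes 6 fell (adjusted p = 4.16e-04). Of 25 collagen genes 3 rose and 8 fell (adjusted p = 0.00149 for falls), and of 9 protocadherins outside the clusters 4 rose and 1 fell (adjusted p = 0.0129 for rises). Of the clustered protocadherins 2 of 3 rose, which did not pass (Fisher's exact adjusted p = 0.0524), nor did HOX genes, histones, solute carriers and ribosomal proteins. HOX genes passed for falls without replicate 1 labelled knockout, with 17 of 35 lower and 6 higher (Fisher's exact adjusted p = 0.0222). Leaving out replicate 1 labelled knockout, 215 of 445 zinc finger genes rose and 50 fell (adjusted p = 5.47e-26), 8 of 11 MAGE and cancer-testis genes fell (0.00939), 8 of 25 collagen genes rose and 12 fell (0.0689, no longer past the threshold) and 4 of 9 other protocadherins rose and 2 fell (0.443, likewise). With a WT library left out, 41 to 43 zinc finger genes rose, 3 to 4 MAGE and cancer-testis and 4 collagen genes fell. Over the 6 libraries left out in turn, Fisher's exact adjusted p reached 6.85e-17 for zinc finger rises and 0.00939 for MAGE and cancer-testis falls, and that of the clustered protocadherins ran from 0.00341 to 0.311. For the other protocadherins it was 0.111 and 0.165 without replicates 2 and 3 labelled knockout. Genes of a family are not independent, and the families were chosen on these data.

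Calls were uneven between chromosomes, which was not tested. Whether a difference between clones or the guide lies behind this, and behind the gene families above, cannot be told from these libraries. Of 309 tested protein-coding genes on chromosome 22, 83 fell and 4 rose (median log2 fold change -0.59, and -0.46 without replicate 1 labelled knockout), and of 494 on chromosome 4, 164 rose and 18 fell (median 0.55, and 0.35 without that library). Genes with at least 5 CPM in 1 group and at most 3 counts in each library of the other numbered 25 on and 18 off in the libraries labelled knockout, and 0 in each other split. Each other split put WT libraries and libraries labelled knockout on both sides. These genes could hardly meet the rule there, so no conclusion is drawn from the 0.

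The MT-CYB to MT-ND1 coverage ratio was lower in each library labelled knockout. The bias of replicate 1 is argued against by replicate 2, the higher of the other 2, at 0.752, below each WT library. For replicates 2 and 3, fragmentation is argued against by log2 coverage of the 3-prime over the 5-prime part within 6 long mRNAs. The move of this value had a median of -0.0801 and was at most 0.136 in absolute value, against -1.59 for the ratio in replicates 2 and 3. In replicate 1 the value of MT-ND4 was -0.35 against 0.13 in WT and that of MT-ND2 0.051 against 0.57. Only MT-ND5 moved the other way, at 0.27 against 0.12. Fragmentation is therefore not argued against for replicate 1. A decline with distance from the start of heavy-strand transcription is a candidate explanation. Across 14 regions without replicate 1, Spearman's rho of coverage change with position was -0.789 (permutation p = 0.00115). Pearson's r was -0.783 (permutation p = 2.00e-04). It was -0.797 without the 2 regions farthest from the median position, MT-RNR1 and MT-RNR2. MT-CYB and MT-ND1 were kept among the regions, so whether the trend holds without MT-CYB was not tested. Regions are not independent. Slopes of log2 coverage per kb over mRNA genes were -0.0463, -0.116 and -0.128 in replicates 1 to 3 labelled knockout, with replicate 1 the nearest to WT, and -0.0230, -5.36e-04 and 0.0223 in WT (exact permutation p = 0.1, the smallest possible), while with the rRNA genes included they were -0.0935, -0.0939 and -0.0925 against -0.0177, 3.88e-04 and 0.0158. A difference between clones, unrelated to C17orf80, stays open and untested.

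The C17orf80 count was higher, not lower, in the libraries labelled knockout, and at 0.64 ± 0.10 without replicate 1, so the bias of that library alone is argued against. A gain of the surrounding region may contribute. The 20 nearest tested protein-coding genes (chromosome 17, positions 68535116 to 74861532) had a median log2 fold change of 0.51 (95% bootstrap interval 0.24 to 0.76). Of these genes 15 were above 0, while edgeR called 5 higher and 1 lower (KIF19, -3.52). The interval overlaps the value of C17orf80 within its error, so a regional gain and a change of this gene cannot be told apart. A wrong label for the group was not tested.

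With 10 splits of 6 libraries into 3 and 3, no share under 0.05 can be reached. The real split called 2641 genes and the highest other 0 (1 of 10 splits as large), and 10 windows of own-share coverage against 0 (1 of 10). For regions and windows at the deposited scale the real split and the highest other both called 0 by limma (10 of 10), with 1 region and 15 windows at an unadjusted p under 0.05. For lists the real split called 1 and the highest other 6 (10 of 10), for a reason that was not tested.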
